A study of Danio rerio with 24 samples.

How the data were processed

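RNA of whole zebrafish embryos was sequenced from 3 lines, WT, slincRosu3 and BigD, with 4 numbered replicates of each line and treatment, 24 samples in all. Treatment was 1 ng/mL TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, a potent agonist of the aryl hydrocarbon receptor, AHR) or control, with exposure from 6 hours post fertilization (hpf) and collection at 48 hpf. Sequencing was paired-end on a BGI DNBseq instrument, per the labels. The line slincRosu3 carries a CRISPR-Cas9 mutation in slincR, the sox9b long intergenic noncoding RNA, per the series title. What BigD is was not given in the sources used here, no column of the deposited tables carries that name, and its 8 samples were not analysed here.

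The submitters' processing notes name HISAT2 and STAR as aligners, DESeq2, and the build GRCz11. Their versions, the counting program, the annotation and the strand setting were not given in the sources used here. The main table holds raw counts per Ensembl gene for 16 libraries and 26347 genes, deposited by the authors as the sum of 2 read files per sample with zero-count and low-count genes already removed, per the file headers and the name the authors gave the table. In 1 of its columns, deposited as estimated counts by the form of its values, a single value of 26347 was not whole, and it was rounded before use. A second deposited table gives raw counts of 32520 genes for each of the 2 read files of the 8 WT samples, together with reads that the authors' counting assigned to no gene. The authors also deposited log2 fold changes and adjusted p-values from DESeq2, per the file headers and the submitters' processing notes, and these were used only for comparison.

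Several checks preceded the tests. The summed WT counts of the second table equalled those of the main table for all 26347 shared genes in each WT library. The 6173 genes that the authors had removed held at most 15 counts each over the 8 WT libraries. A first sheet of raw counts was not used: 12 of the 12 WT columns checked there held the values of another library than the one named. Another 48 columns under a name that no label explains were not used either. None of the 24 pairs of libraries within a group was identical. Gene symbols were the authors' for 21133 genes and came from a gene name table for 3216, which left 1998 genes without a symbol. No annotation of GRCz11 was at hand, so no coordinates are given, and a gene table of the assembly GRCz12tu served only for which genes share the chromosome of sox9b.

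Total counts per library ran from 17275522 to 20100736. In the WT libraries the authors' counting assigned 39.8% to 43.2% of reads to a gene and 52.3% to 55.3% to no feature, and 4.1% to 4.88% were not unique. With the strand setting unknown, reads assigned to no feature need not lie outside annotated genes. Without a stated strand setting, overlapping and antisense genes cannot be told apart. Reads of near-identical genes (the mhc1u, ugt1b, hsp70, vtg and myosin heavy chain families, and tandem copies such as ggact.2, itga2.3 and c3a.3) could have been split or dropped by the authors' counting, so values of those genes are uncertain. Floors and counting intervals cover counting error only.

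The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM scaling, filterByExpr by group (20907 genes kept) and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. It was planned for 24 samples in 6 groups. With no BigD columns, 16 libraries in 4 groups were fitted together, which left 12 residual degrees of freedom. Contrasts were TCDD against control in each line, slincRosu3 against WT at each treatment, and the difference of the TCDD effects. CPM below are counts scaled to a common library total with TMM, given as mean ± SD over 4 libraries. Log2 fold changes carry their standard error (SE).

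Gene lists (26 with at least 5 measured members) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. The contrasts, the lists, the tests and the rule for named genes were chosen before the data were examined. Under that rule each contrast names the 10 genes (5 for slincRosu3 against WT with TCDD and for the difference of effects) with the largest rise and the largest fall. These had to be past the threshold, without overlap between the groups (not required for the difference of effects), at a mean of at least 1 CPM in the higher group, and with a symbol that is not a clone or locus name. The rule adds the 3 smallest p-values, a fixed set (slincR, sox9b, sox9a, ahr2, cyp1a, cyp1b1, cyp1c1, cyp1c2, ahrra and tiparp), and up to 4 members past the threshold per list. A few genes that the rule takes are left out of the text.

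Alternatives fixed together with these tests were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Fits without 4 libraries that stand apart on the first principal component, without WT control 1 and 2 together, of the WT libraries alone on the unfiltered table with no filter on low counts, and with fry's groups in reverse order were added after seeing the data. The tests were tried on simulated counts drawn from the real means and library sizes, with genes changed 2-fold and 4-fold. Each gene was drawn independently, so the simulated libraries lacked structure across genes such as the first principal component of the real ones. The shares recovered and the false calls therefore hold only for libraries without such structure. The share recovered was 73% and 93.9% for TCDD in WT (20660 genes), 77.8% and 90.9% for TCDD in slincRosu3 (20686 genes), 78% and 83.8% for the lines without TCDD (20659 genes), 77% and 89.9% with TCDD (20694 genes), and 51% and 77% for the difference of effects (20655 genes), with 3 to 15 false calls per contrast. Tables were prepared with Python 3.11.15 and pandas 2.3.3.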

Results

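Expression was compared in 16 whole-embryo libraries: WT control, WT TCDD, slincRosu3 control and slincRosu3 TCDD, with 4 libraries each. Total counts ran from 17275522 in slincRosu3 TCDD 1 to 20100736 in WT TCDD 4. Between 24778 and 25471 genes had at least 1 count. Across log2 CPM, the first principal component held 29.8% of the variance and did not follow line or treatment. Its highest scores were 56.19 in WT control 4, 53.42 in slincRosu3 control 4, 35.49 in WT TCDD 4 and 32.71 in WT TCDD 3, and the next was 18.06 in WT control 1. In those 4 libraries the 100 most abundant genes took 38.4%, 36.2%, 35.3% and 36.1% of counts, against at most 35.1% in the other 12. The second component, with 16.7%, separated the lines.

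**Figure D1:**
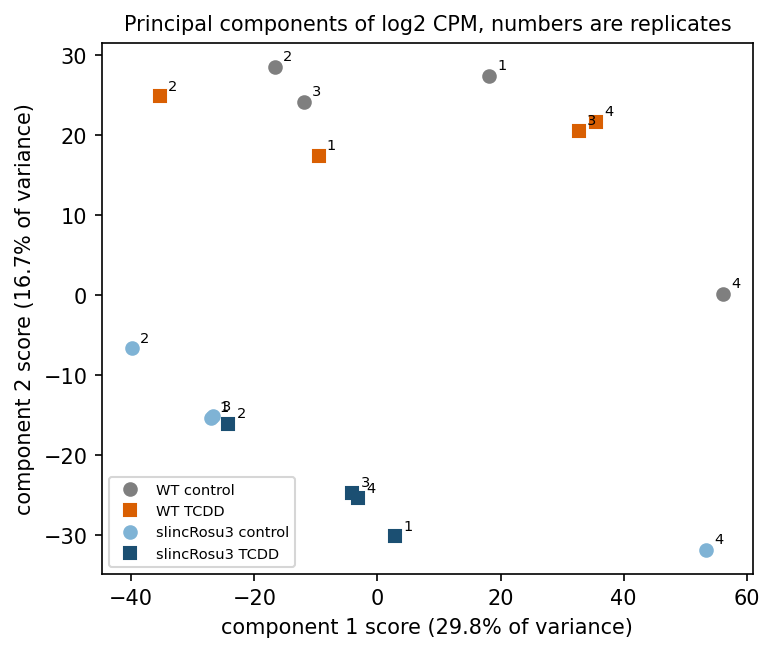
Scores of the 16 libraries on the first component (horizontal, 29.8% of variance) and the second (vertical, 16.7% of variance) of log2 CPM, with replicate numbers beside the points. Color and shape give the group; WT control 4, WT TCDD 3 and 4 and slincRosu3 control 4 lie at 32.71 or higher on the first component.

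The edited gene, slincR, has no gene in the main table under that name or under the symbol of the reference gene list, so it is not analysed here and cannot check the line labels. Its neighbor sox9b (ENSDARG00000043923), a transcription factor of cartilage and neural crest development, stood at 140 ± 21.7 CPM in WT control and 108 ± 15.5 CPM in slincRosu3 control (SD, n = 4 each). That log2 difference of -0.37 (SE 0.214) did not pass edgeR's test (adjusted p = 0.559). With TCDD its mean was 89.6 ± 33.8 CPM in WT and 79.3 ± 16.4 CPM in slincRosu3, log2 changes of -0.64 (adjusted p = 0.414) and -0.45 (adjusted p = 0.999) from control by the same test. In WT TCDD 1 and 2 it stood at 67.05 and 57.82 CPM, against 112.1 to 159.1 CPM in WT control. In WT TCDD 3 and 4, which stand apart on the first component, it stood at 131.5 and 102.1 CPM. The missing call in WT therefore does not show that TCDD leaves sox9b unchanged. Its paralog sox9a (ENSDARG00000003293) had log2 changes of -0.02 in WT and 0.06 in slincRosu3. Treatment labels could be checked: cyp1a stood at 856 CPM or more in each of the 8 TCDD libraries and at 5.32 CPM or less in each of the 8 control libraries.

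TCDD against control in WT asks which transcripts the dioxin changed in unedited embryos. The gene cyp1a (ENSDARG00000098315), the cytochrome P450 commonly read as the marker of AHR activation, rose from 3.59 ± 1.01 to 1078 ± 160 CPM (SD, n = 4 each), 302-fold. Its relatives cyp1c1 (ENSDARG00000101195) and cyp1c2 (ENSDARG00000101789) rose 40.6-fold and 28.2-fold, and cyp1b1 (ENSDARG00000068934) rose 4.02-fold. The AHR repressor gene ahrra (ENSDARG00000099702) rose 36.1-fold, from 0.402 ± 0.0608 to 14.7 ± 1.43 CPM. The receptor gene ahr2 (ENSDARG00000021833) rose 1.95-fold and tiparp, a poly(ADP-ribose) polymerase gene induced through AHR, rose 1.67-fold. Of the same list of AHR target genes, wfikkn1, which encodes a secreted myostatin-binding protein, rose 8.72-fold and the forkhead gene foxq1a 8.7-fold. Outside that list, rises were seen in the growth factor gene fgf7 (12.7-fold), ifitm1 (9.48-fold), the chemokine gene cxcl19 (6.91-fold) and the chemokine receptor gene ccr9a (4.6-fold). Genes that fell included prl, which encodes prolactin (3-fold), the Notch-responsive her4.3 (2.66-fold), the chemokine gene cxcl12b (1.67-fold) and the endothelial scavenger receptor gene stab2 (1.45-fold).

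By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 68 of 20907 genes changed in WT, 62 higher and 6 lower, and cyp1a had the smallest adjusted p, 2.83e-14. Among 18 measured AHR target genes 12 rose and none fell (16 rose and 1 fell when adjusted over the list alone; camera adjusted p = 3.82e-50). Among 24 genes of matrix remodelling and regeneration 2 rose, the metalloproteinase genes mmp13a (2.94-fold) and mmp9 (1.72-fold), or 7 adjusted over the list alone (camera adjusted p = 1.49e-05). Both lists hold with an estimated correlation, at adjusted p = 6.38e-05 and 0.0333. Wnt signalling passed camera as higher (1 of 26 genes, the Wnt inhibitor notum1b at 1.6-fold; 2 adjusted over the list alone) but not with an estimated correlation (adjusted p = 0.0535). The lists of photoreceptor and retina, Nrf2, neurons, circadian clock and glucocorticoid response were also higher by camera, and those of cell cycle, glia, heat shock and skeletal muscle lower, with adjusted p from 0.189 to 0.655 with an estimated correlation. Over all genes tested no member of these 9 lists rose. Adjusted over the list alone, 3 circadian, 3 Nrf2 and 1 glucocorticoid response genes rose and 3 glial genes fell. Camera's call was lost for neurons (adjusted p = 0.187) and heat shock (0.187) without WT control 1, Nrf2 (0.105) without WT TCDD 3, glucocorticoid response (0.118) without WT control 2 and skeletal muscle (0.817) without WT control 4. Beside these lists, WT control 1 had the highest cell cycle score (0.694 on the centred log2 scale) and the lowest photoreceptor score (-0.708), and WT TCDD 1 and 2 the highest circadian scores (0.382 and 0.418). The AHR target score was 1.25 and 1.23 in WT TCDD 1 and 2 and 0.946 and 0.994 in WT TCDD 3 and 4. The other 14 lists did not pass, with camera adjusted p from 0.0591 to 0.929. They include innate immunity, in which mmp13a, mmp9 and the cytokine gene il1b (4.29-fold) rose, while the median and mean of the list were positive and its test pointed down. They also include AHR pathway components, with ahr2 higher, blood vessel endothelium, with stab2 lower, and hypoxia, whose median and test were positive and whose mean was negative. Adjusted over the list alone, innate immunity had 4 higher and 2 lower, blood vessel endothelium 1 higher and 2 lower, retinoid metabolism 1 higher and 1 lower, and bone 1 higher.

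The WT count was 26 in a fit of the WT groups alone, 147 by DESeq2's Wald test, 327 without the 4 libraries high on the first component, 27 without WT control 1 and 2 together, and 30 with the WT libraries alone, the unfiltered WT table and no filter on low counts together. Leaving out 1 library ended 9 of the 22 calls taken by the rule for named genes (adjusted p up to 0.199), among them cxcl19 without WT control 2, and her4.3, tiparp, prl, stab2, cxcl12b, il1b and notum1b without any of 4 to 6 of the 8 libraries, WT control 1 and WT TCDD 1 among them each time.

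**Figure D2:**
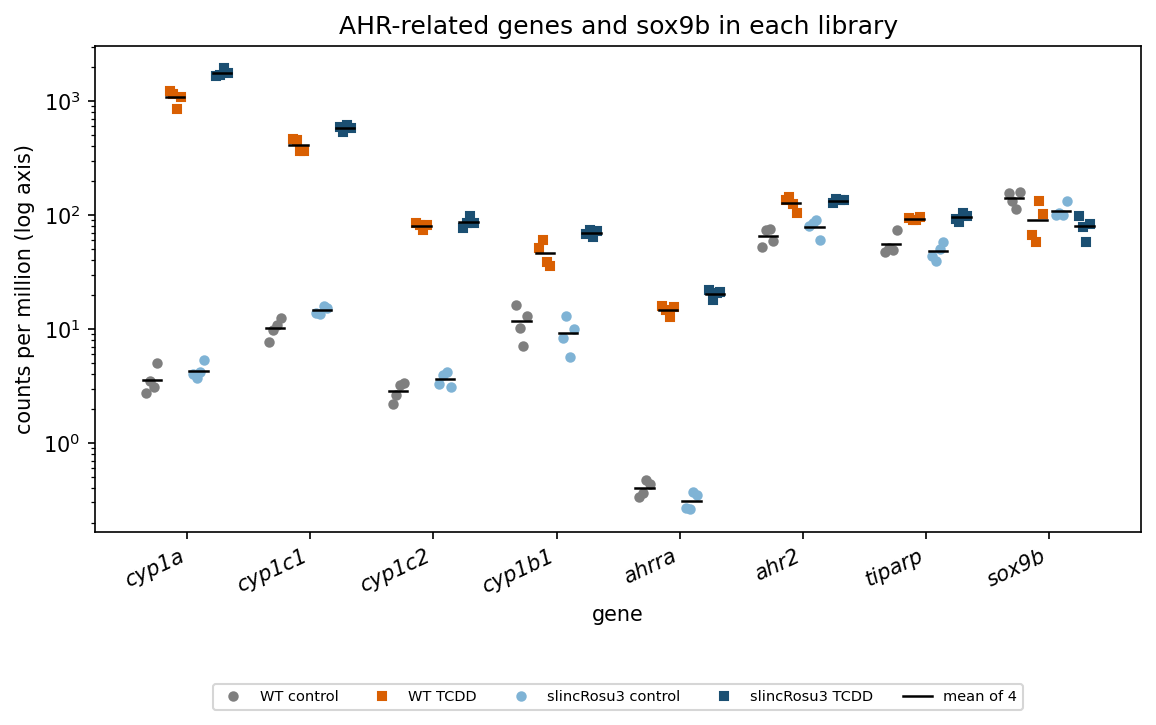
CPM on a log axis (vertical) of 7 AHR-related genes and sox9b in each of the 16 libraries, colored by group, with a line at the mean of 4. The WT means of cyp1a are 3.59 CPM in control and 1078 CPM with TCDD, and the groups of sox9b overlap in WT.

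TCDD against control in slincRosu3 asks the same of the mutant line. There cyp1a rose from 4.32 ± 0.702 to 1756 ± 124 CPM (SD, n = 4 each), 407-fold, ahrra rose 64.6-fold, cyp1c1 39.7-fold, cyp1c2 23.8-fold and cyp1b1 7.5-fold. The second AHR repressor gene ahrrb rose 13.9-fold, ahr2 1.7-fold and tiparp 1.99-fold. Genes wfikkn1 (23.9-fold), fgf7 (15.9-fold), cxcl19 (7.21-fold) and mamdc2b (6.05-fold) were also among the largest rises. Heme oxygenase gene hmox1a rose 2.24-fold and the glutathione transferase gene gstp1 1.61-fold. The named genes that fell were lgals3bpb (2.53-fold), the fatty acid binding protein gene fabp11b (1.86-fold), the glutathione transferase gene gstm.3 (1.64-fold), cfd, which encodes complement factor D (1.5-fold), the Wnt antagonist gene sfrp2 (1.44-fold) and the endothelial gene plvapb (1.42-fold).

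In this line edgeR's quasi-likelihood test called 80 genes, 74 higher and 6 lower. Of 18 AHR target genes 14 rose (15 adjusted over the list alone; camera adjusted p = 3.21e-76), and of 22 Nrf2 genes, which respond to oxidative stress, 2 rose (6 adjusted over the list alone; camera adjusted p = 3.19e-08). These lists hold with an estimated correlation, at adjusted p = 6.69e-06 and 0.0322, and share gstp1. Matrix remodelling was higher by camera with 3 of 24 genes (mmp13a 3.48-fold, mmp9 1.91-fold, msx2b 1.69-fold; 5 adjusted over the list alone), without holding under an estimated correlation (adjusted p = 0.14). Wnt signalling was higher with the inhibitor genes dkk1a (2.06-fold) and notum1b (1.58-fold) up and sfrp2 down (3 up and 1 down adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Hypoxia and erythroid lists were higher and cartilage, lens, photoreceptor and cell cycle lists lower by camera, none with a member past the threshold over all genes (1 erythroid gene higher adjusted over the list alone), and with adjusted p from 0.162 to 0.573 with an estimated correlation. The erythroid score was highest in slincRosu3 TCDD 1 (0.545), and camera's call was lost for erythroid (adjusted p = 0.367) without that library and for Wnt signalling (0.13) without slincRosu3 control 4. The other 16 lists had camera adjusted p from 0.104 to 0.955. Among them were innate immunity with 3 genes higher (mmp13a, mmp9 and the cathepsin gene ctss2.1), bone with msx2b higher, blood vessel endothelium with plvapb lower, and AHR pathway components with ahr2 higher. Adjusted over the list alone, innate immunity had 3 higher and 4 lower, bone 1 higher and 4 lower, blood vessel endothelium 2 higher and 2 lower, glucocorticoid response 2 higher and neural crest 1 lower. In AHR pathway components and in neurons, median and mean were negative and the test pointed up; median and mean differed in sign for neural crest, circadian clock and glia.

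The slincRosu3 count was 157 by DESeq2, 170 without the 4 libraries high on the first component, and 46, 53 and 51 without slincRosu3 control 1, slincRosu3 control 2 and slincRosu3 TCDD 1. Leaving out 1 library ended 11 of the 26 named calls (adjusted p up to 0.187): ahr2 without slincRosu3 control 1 or TCDD 2 or 4, msx2b without control 1 or 2 or TCDD 1, dkk1a without control 1 or 2 or TCDD 1 or 3, and the 6 genes that fell, notum1b and ctss2.1 without any of 5 to 8 of the 8 libraries.

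The responses of the lines shared 49 genes, all higher with TCDD, against 0.219 for independent lists of the same sizes; no library is shared by both contrasts. None of the 6 genes lower in either line was lower in both at the threshold. Yet prl, cxcl12b and stab2, called in WT, and plvapb, sfrp2, cfd and fabp11b, called in slincRosu3, had negative log2 changes in both lines (-0.16 to -1.58 in WT, -0.39 to -1.06 in slincRosu3). They passed edgeR's test of the TCDD effect averaged over both lines (adjusted p from 0.00104 to 0.0448), which was added after the data were seen. The average reuses the libraries in which each gene was called, so passing is not separate evidence of a fall in the other line. The other genes called lower in a single line did not pass the averaged test. Across the 99 genes changed in either line Pearson's r of the log2 changes was 0.937 and Spearman's rho 0.805, and 95 had the same sign. Those genes were picked for a change in these data, and genes are not independent replicates. Across all 20907 genes r was 0.211 and rho 0.062.

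**Figure D3:**
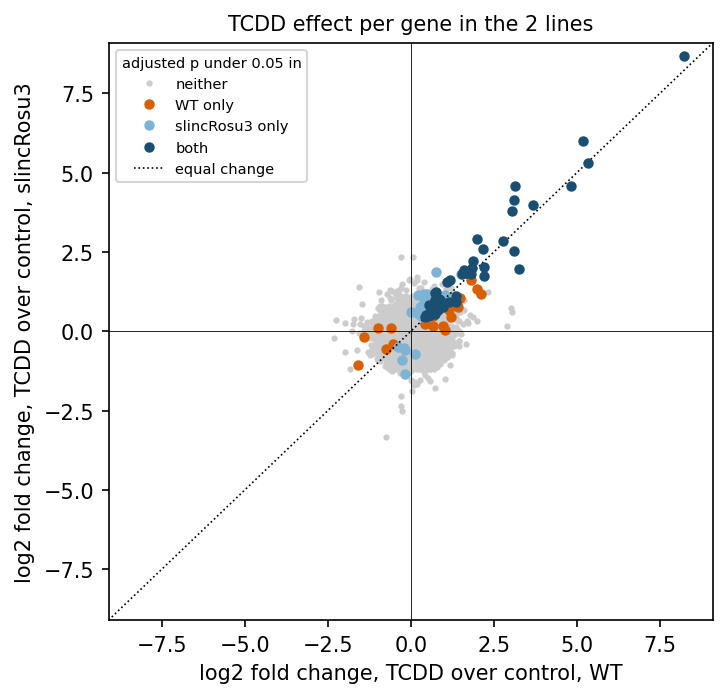
Log2 fold change with TCDD of each of 20907 genes in WT (horizontal) and slincRosu3 (vertical), colored by the line in which the adjusted p was under 0.05; the dotted line marks equal change. The 49 genes called in both lines lie in the upper right, with cyp1a at 8.24 and 8.67.

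The difference of the TCDD effects asks whether the mutation alters the response. No gene passed: edgeR's quasi-likelihood test called 0 of 20907 (899 at an unadjusted p under 0.05) and DESeq2 called 0. The log2 difference for cyp1a was 0.43 (SE 0.234), for ahrra 0.84 (SE 0.264), for cyp1b1 0.9 (SE 0.335) and for ahr2 -0.21 (SE 0.193), each with adjusted p = 0.996. The smallest p-values belonged to si:ch73-167f10.1, coch, expressed in the inner ear, and the acyl-CoA synthetase gene acsl2 (adjusted p = 0.946 each). By camera 16 of 26 lists differed, with AHR target genes, erythroid, muscle, heart, epidermis, Nrf2, cell cycle, glia, heat shock and hypoxia lists higher in slincRosu3 relative to WT and photoreceptor, lens, cartilage, bone, neuron and circadian lists lower. None holds with an estimated correlation (adjusted p from 0.463 to 0.633), and none has a member past the threshold over all genes, though adjusted over the list alone 1 photoreceptor gene was higher and 2 bone genes lower. The other 10 lists had camera adjusted p from 0.0963 to 0.774; in glucocorticoid response, liver and yolk, AHR pathway components and neural crest the median and mean differed in sign, and in p53 response both were negative and the test pointed up. Without the 4 libraries high on the first component 20 genes passed, 8 higher and 12 lower.

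The line contrast without TCDD asks what the mutation changes in untreated embryos. The myosin heavy chain gene myhc4 (ENSDARG00000035438) was higher in slincRosu3, at 173 ± 27 against 43.6 ± 5.96 CPM (SD, n = 4 each), and myha 4-fold higher, while the cardiac actin gene actc1a (ENSDARG00000042535) was lower, at 144 ± 62.3 against 618 ± 192 CPM, and the cardiac transcription factor gene nkx2.5 1.98-fold lower. The Argonaute gene ago2, which acts in RNA interference, was 5.02-fold higher, the complement gene c3a.3 4.5-fold, ggact.2 5.35-fold and the macrophage gene mpeg1.1 1.69-fold. Other large rises were itga2.3, an integrin gene (6.82-fold), the protocadherin gene dchs2 (5.26-fold), ifitm1 (4.92-fold), the leukotriene synthase gene ltc4s (4.65-fold) and the glucose transporter gene slc5a2 (3.79-fold). High itga2.3 was not confined to slincRosu3 libraries (2.049 to 6.515 CPM over both treatments). It stood at 3.652 and 2.677 CPM in WT TCDD 3 and 4, against 0.4329 and 0.4137 CPM in WT TCDD 1 and 2. The potassium channel gene kcnk5a (ENSDARG00000023587) was 4.95-fold lower, cyp1d1 1.81-fold and the epidermal keratin gene cyt1l 1.87-fold. Also lower were cd28l (5.32-fold), cyp2p9 (5.13-fold), the glucuronosyltransferase gene ugt2a6 (3.72-fold), the vitellogenin gene vtg7 (3.48-fold), the steroid dehydrogenase gene hsd3b2 (3.47-fold) and prozb (3.38-fold). The class I major histocompatibility gene mhc1uma had 0 counts in the 4 slincRosu3 control libraries and 137 in WT control, at least 46.9-fold lower with a floor of 3 counts over the group. Its relative mhc1ula had 1 count against 119, a scaled ratio of 122 (95% counting interval 21.5 to 4870).

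In this contrast 321 genes differed by edgeR's quasi-likelihood test, 136 higher and 185 lower in slincRosu3. The smallest adjusted p, 5.14e-07, was that of ggact.2, followed by si:ch1073-190k2.1 (5.99-fold lower) and ENSDARG00000103590 (3.62-fold lower). None of the lists that passed held with an estimated correlation. They were photoreceptor (higher, adjusted p = 0.849 with that correlation), cartilage (higher, 0.849), cell cycle (lower, 0.849), glia (lower, 0.771) and innate immunity (higher, 0.543). Only innate immunity held a gene past the threshold, mpeg1.1, or 2 adjusted over the list alone. WT control 1, with the highest cell cycle and lowest photoreceptor score, is part of this contrast. Skeletal muscle had none of 31 genes past the threshold (camera adjusted p = 0.525). Heart muscle had 2 of 21 genes lower (actc1a and nkx2.5; camera adjusted p = 0.65) and AHR target genes 1 of 18 lower (cyp1d1; 2 higher and 2 lower adjusted over the list alone). These and epidermis, with cyt1l lower (2 higher and 2 lower adjusted over the list alone), were among the 21 lists with camera adjusted p from 0.0537 to 0.988. Adjusted over the list alone, liver and yolk had 2 higher and 1 lower and heat shock 1 lower. Median and mean differed in sign for heart, Wnt signalling and AHR pathway components, and in hypoxia and heat shock both were negative and the test pointed up.

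The count without TCDD was 149 in a fit of the groups alone, 499 by DESeq2, 604 without the 4 libraries high on the first component, 109 without WT control 1 and 2 together, and 176, 198 and 187 without slincRosu3 control 1, 2 and 3. Leaving out 1 library ended 9 of the 26 named calls (adjusted p up to 0.152), nkx2.5 without WT control 4 or slincRosu3 control 1 or 3, cyt1l without slincRosu3 control 1, 2 or 3, itga2.3 without WT control 1 or 2 or slincRosu3 control 2, and ifitm1, cd28l, prozb, vtg7, cyp2p9 and hsd3b2 without any of 4 to 7 libraries, slincRosu3 control 1 and 3 among them each time; the lists of photoreceptor (0.293), cell cycle (0.43) and cartilage (0.278) lost their camera call without WT control 1, glia (0.106) without WT control 4 and innate immunity (0.122) without slincRosu3 control 4.

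**Figure D4:**
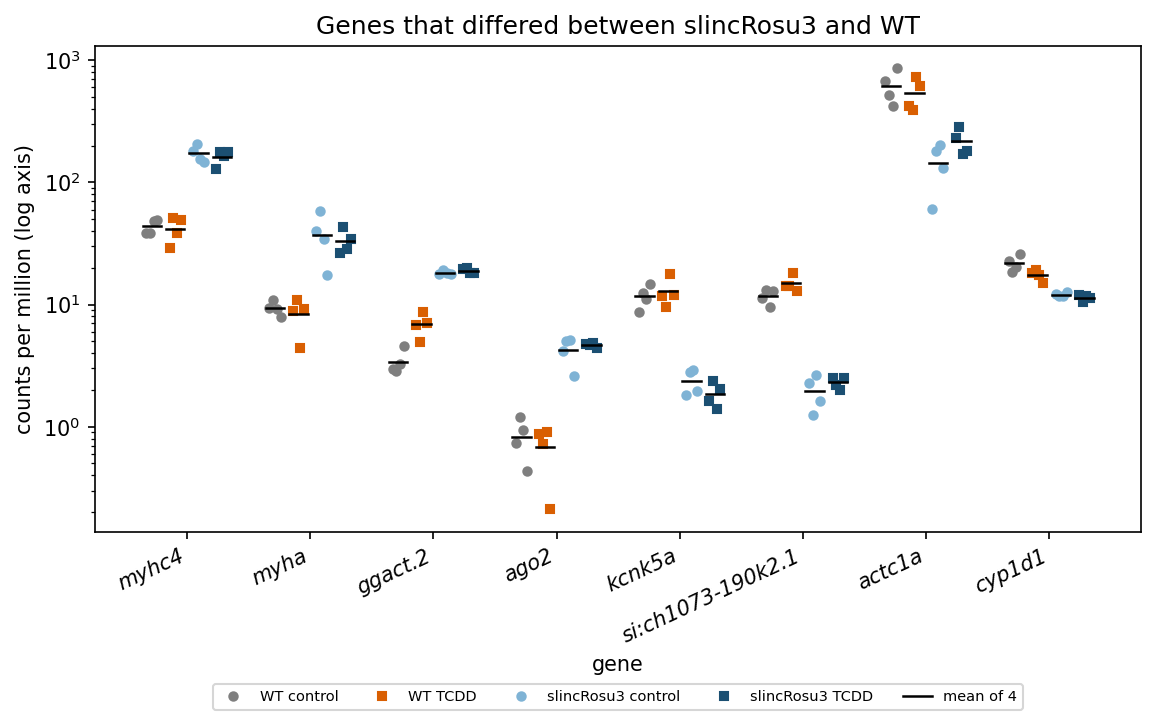
CPM on a log axis (vertical) of 8 genes that differed between the lines, in each of the 16 libraries, colored by group, with a line at the mean of 4. Means of kcnk5a are 11.8 and 12.8 CPM in the WT groups and 2.37 and 1.86 CPM in slincRosu3.

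With TCDD, the line contrast asks how treated mutant and WT embryos differ. Several of the same genes differed as without TCDD: myhc4 was 3.86-fold, myha 3.96-fold and ago2 6.83-fold higher, and kcnk5a 6.86-fold, actc1a 2.51-fold and cyp1d1 1.54-fold lower in slincRosu3. The transcript cyp1a was 1.63-fold higher, at 1756 ± 124 against 1078 ± 160 CPM (SD, n = 4 each; adjusted p = 0.0151 by edgeR's quasi-likelihood test), ahrra 1.39-fold, cyp1c1 1.41-fold and the cathepsin gene ctsl.1 1.78-fold. Log2 differences of cyp1c1 and ctsl.1 were about as large without TCDD (0.525 and 0.826, not past the threshold) as with it (0.493 and 0.832). Those of cyp1a and ahrra were 0.272 and -0.367 without TCDD, against 0.704 and 0.472 with it. Heat shock genes hsp70.1 (3.41-fold), hsp70.3 (3.21-fold), hsph1 (1.71-fold) and dnajb1b (1.61-fold) were higher, as were the epidermal genes krt17 (2.04-fold) and anxa1a (1.71-fold), the coagulation factor gene f13a1a.1 (6.73-fold), the sialyltransferase gene st3gal1l (3.85-fold) and the vitellogenin gene vtg1 (3.17-fold). The clock gene nr1d1 was 3.93-fold, the phosphatidylinositol transfer gene pitpnc1 4.64-fold, mhc1uba 13.6-fold, the antiproliferative gene btg2 1.81-fold and the glial gene fabp7a 1.38-fold lower. Much of the nr1d1 difference came from WT TCDD 1 and 2, at 3.139 and 2.741 CPM. WT TCDD 3 and 4 stood at 0.9668 and 0.9448 CPM, against 0.2215 to 0.5967 CPM in slincRosu3 TCDD. The groups of btg2 overlapped, at 88.97 CPM in WT TCDD 4 and 93.14 CPM in slincRosu3 TCDD 4. For mhc1ula 0 counts stood against 128 in WT TCDD, at least 40.4-fold lower with a floor of 3 counts over the group, and mhc1uma had 2 counts against 116, a scaled ratio of 54.9 (95% counting interval 14.9 to 459).

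Here 389 genes differed by edgeR's quasi-likelihood test, 185 higher and 204 lower. The smallest adjusted p, 1.51e-06, was shared by si:ch73-329n5.1 (21.5-fold higher) and si:ch1073-190k2.1 (6.48-fold lower), followed by si:ch211-121a2.2 (167-fold lower). Of the genes that differed without TCDD, 70 were also higher and 91 also lower with TCDD, against 1.2 and 1.81 for independent lists; these contrasts share no library. Lens and photoreceptor lists were lower and innate immunity higher by camera, with no gene past the threshold in any of them. Adjusted over the list alone 8 of 25 innate immune genes were higher and 1 lower. Adjusted p with an estimated correlation was 0.881, 0.881 and 0.0807, so none of the 3 holds. The other 23 lists had camera adjusted p from 0.0787 to 0.99, among them AHR target genes with 4 higher and 1 lower of 18, heat shock with 4 higher of 21, and epidermis with 2 higher of 25. Adjusted over the list alone, matrix remodelling had 2 higher and 6 lower, liver and yolk 5 higher and 4 lower, epidermis 4 higher and 1 lower, heat shock 5 higher, Nrf2 2 higher and 1 lower, heart 1 higher and 2 lower, hypoxia 1 higher, neural crest 2 lower, glia 2 lower and retinoid metabolism 1 lower. Median and mean differed in sign for matrix remodelling and glia.

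The count with TCDD was 674 by DESeq2, 697 without the 4 libraries high on the first component, 243 without WT TCDD 1, and 175, 194 and 180 without slincRosu3 TCDD 1, 2 and 4. Leaving out 1 library ended 16 of the 30 named calls (adjusted p up to 0.18), those of mhc1uba without slincRosu3 TCDD 1, 2 or 4, pitpnc1 without slincRosu3 TCDD 1, 3 or 4, and actc1a, ahrra, fabp7a, vtg1, cyp1c1, ctsl.1, nr1d1, btg2, krt17, anxa1a and the heat shock genes, each without any of 4 to 8 of the 8 libraries, slincRosu3 TCDD 1 and 2 among them except for ahrra, which lost its call without slincRosu3 TCDD 1, 3 or 4 or WT TCDD 1, 2 or 3.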

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

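The tests of the agreement between read files, of the AHR target list without WT TCDD 3 and 4, and of its score by permutation, as well as the highest possible share on the chromosome of sox9b and the contrast averaged over lines, were chosen only after the result was seen.

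A library lay far from the other 3 of its group, judged by its gap against the range of the 4, in 19 of 237 groups of 4 examined. Chance gives about 1 in 20 for independent groups of continuous values. These groups share libraries, and where 3 libraries have 0 counts any count in the other is flagged, as for mhc1ula, mhc1uma and mhc1uba below. The number found can therefore not be read against that rate. In slincRosu3 control 4, 24983 genes were detected against 25245 to 25286 in the other 3, sox9a stood at 22.2 CPM against 47.6 to 51 CPM, sox9b at 132 against 99.2 to 103 CPM, and lgals3bpb at 3.01 against 4.37 to 4.63 CPM. In slincRosu3 control 1 cyp2p9 was at 0 CPM against 0.289 to 0.316, and in slincRosu3 control 2 ggact.2 was at 19.2 against 17.9 to 18 CPM and mhc1ula at 0.0521 CPM against 0. In WT control 1 wfikkn1 was at 2.08 against 0.468 to 0.68 CPM, and in WT control 4 nkx2.5 was at 2.68 against 1.85 to 1.98 CPM. In WT TCDD 4 ifitm1 was at 1.31 against 2.54 to 2.74 CPM and hsph1 at 2.89 against 2.33 to 2.42 CPM, in WT TCDD 3 acsl2 was at 17.6 against 20.7 to 21.2 CPM, and in WT TCDD 2 pitpnc1 was at 2.79 against 1.73 to 1.83 CPM. In slincRosu3 TCDD 2 dkk1a was at 3.36 against 3.68 to 3.71 CPM and vtg1 at 2.26 against 1.01 to 1.19 CPM. In slincRosu3 TCDD 3 fabp11b was at 8.18 against 5.49 to 5.73 CPM and mhc1uba at 0.271 CPM against 0, and in slincRosu3 TCDD 4 nr1d1 was at 0.222 against 0.551 to 0.597 CPM and mhc1uma at 0.111 CPM against 0.

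The TCDD effect differed between the lines by camera for 16 lists, none of which holds with an estimated correlation (lowest adjusted p = 0.463). Lists higher in slincRosu3 relative to WT were AHR target genes (camera adjusted p = 0.00681), erythroid (0.000636), skeletal muscle (0.00753), heart muscle (0.0107), cell cycle (0.0107), heat shock (0.0118), glia (0.0118), epidermis (0.0489), Nrf2 (0.0489) and hypoxia (0.0496). Lists lower there were photoreceptor and retina (1.33e-09), lens (6.07e-05), cartilage (0.00753), neurons (0.00912), circadian clock (0.0118) and bone (0.0489). Leaving out 1 library ended 13 of these calls, with the highest adjusted p for AHR targets (0.0728), skeletal muscle (0.328), heart (0.0728), epidermis (0.738) and hypoxia (0.403) without WT control 4, cartilage (0.0647), neurons (0.325), cell cycle (0.607) and heat shock (0.307) without WT control 1, glia (0.0761), circadian clock (0.207) and Nrf2 (0.262) without WT TCDD 2, and bone (0.239) without slincRosu3 control 4.

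WT control 4, WT TCDD 3 and 4 and slincRosu3 control 4 stood apart on the first component. After thinning all libraries to the lowest total, 101% of the gap to the other 12 stayed, and without the 100 most abundant genes 98.8% stayed. Totals differed little even before thinning (17275522 to 20100736), so library size is an unlikely source, but thinning was a weak test of it. The component draws on all 20907 genes tested, so leaving out 100 could change little too. That result argues against those 100 genes alone. It does not test a wider shift that goes with their higher share of counts in these 4 libraries. Across the 8 WT libraries the component rose with the disagreement between the 2 read files of a sample in genes with over 1000 counts (Spearman's rho 0.857, exact permutation p = 0.0107, adjusted 0.0214; Pearson's r 0.717, p = 0.0451, adjusted 0.0902), and without WT TCDD 3 and 4 r was 0.945 (exact p = 0.00833), while the p of rho, 0.0583, missed 0.05. In genes of 20 to 100 counts rho was -0.452 (exact permutation p = 0.267) and r -0.397 (p = 0.325), so the read files do not decide on library preparation or RNA quality. That explanation stays open, with mixed signs that were not tested against the component: WT TCDD 3 and 4 and slincRosu3 control 4 had the fewest genes detected (24778, 24782 and 24983) but WT control 4 had 25181, more than slincRosu3 TCDD 1 and 2 (25143 and 25066), and the mitochondrial share was 6.99% in WT TCDD 3 against 4.24% to 5.22% in the other 15 libraries, the other 3 that stand apart included, while a difference in stage or clutch stays open and untested, since the labels give no batch.

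AHR target genes responded more in slincRosu3 than in WT by camera, with a mean log2 difference of 0.251 over 18 genes. Without WT TCDD 3 and 4 it was 0.15 (SE over the 18 genes 0.147). That SE takes the genes as replicates and does not measure the spread between libraries. These values cannot show whether WT TCDD 3 and 4 account for the difference. The cyp1a difference with TCDD was then 0.57 with adjusted p = 0.0873 by edgeR's quasi-likelihood test, no longer past the threshold. An exact two-sided permutation of the line labels within treatment (4900 assignments) gave p = 0.0829 for the list score, so the spread between libraries may account for the difference. An effect of the mutation on the AHR response stays open.

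Genes differed between slincRosu3 and WT in both treatments, and a candidate explanation other than the mutation is a haplotype carried along with the targeted locus. Even if every gene without a place in the gene table of the assembly GRCz12tu lay on the chromosome of sox9b, at most 33.3% of the genes called without TCDD (28.5% by DESeq2) and 31.1% with TCDD (24.1% by DESeq2) would lie there. That argues against effects of this haplotype on genes of its own chromosome as the source of most of these differences. An effect of the haplotype on genes of other chromosomes cannot be tested by such a share and stays open. DESeq2's calls are counted here only among the genes that edgeR tested, 487 without TCDD and 659 with TCDD. Whether genes changed on its own chromosome add a smaller part stays open. An upper bound under 2, set beforehand as evidence against the haplotype, was met with enough genes placed (80.9%) only for DESeq2's calls with TCDD (6.19% against 5.06% of other genes). There Fisher's exact odds ratio was 1.24 (0.838 to 1.78, p = 0.231), and that range still holds a small excess. The same Fisher's exact test is void for edgeR's calls with TCDD (7.59% against 5.05%; odds ratio 1.54, upper bound 2.4, p = 0.0585) and for the calls without TCDD by edgeR (7.36% against 5.06%, 1.49, upper bound 2.45, p = 0.129) and DESeq2 (6.45% against 5.07%, 1.29, upper bound 1.97, p = 0.232), because 74.6%, 72% and 76.4% of the genes could be placed, under the 80% required. Other background differences between the lines, among them the mhc1u genes, stay open in both treatments, and a test of neighbouring genes for them was dropped before it was run for the same lack of placed genes.

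Other splits of the same libraries were counted, in fits of the groups compared. For slincRosu3 against WT the real split was the single one of 35 to give as many genes. It gave 149 genes against at most 1 in any other without TCDD and 363 against at most 18 with TCDD. That argues against chance, but 1 in 35 is the lowest share these splits can give, so they cannot exclude it. They also cannot tell the mutation from any other difference between the lines. For TCDD in WT 2 of 35 splits gave at least the real 26 genes, and for TCDD in slincRosu3 2 of 35 gave at least the real 98, so the splits do not exclude chance for these counts. The other split was WT control 1 and 4 with WT TCDD 3 and 4 against the rest, with 890 genes, which points to a structure of the samples, and slincRosu3 control 1, 2 and 3 with TCDD 2 against the rest, with 122. Yet 49 genes were higher with TCDD in both lines in the fit of all groups, against 0.219 for independent lists of 62 and 74 genes, and these contrasts share no library, which argues against chance as the source of those 49, although genes are not independent and the fit shares its dispersions. For the difference of effects the real count was 0, so that all 100 of 100 draws had to give as many and the count says nothing about chance; the highest other was 151. For the averaged TCDD effect 1 of 100 draws, the real one, gave 168 genes and the highest other 0; an earlier set of 50 draws had 2 as large, the highest other at 1045 genes. In that draw the 4 libraries high on the first component were all on the same side, which points to a structure of the samples. The share lies under 0.05 in both sets.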

How the results depend on the processing

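The fits without the 4 libraries high on the first component, without WT control 1 and 2 together and on the unfiltered WT table, and fry with the groups in reverse order, were chosen after the data were seen. DESeq2 size factors, no filter on low counts and the replicate number as a block kept every count of genes within 1.5 times: 67, 66 and 80 genes for TCDD in WT, 85, 77 and 96 in slincRosu3, 316, 329 and 370 for the lines without TCDD, 396, 379 and 505 with TCDD, and 0 for the difference of effects. The replicate numbers were not taken to pair the libraries. None of the 4 pairs of groups tested directly against each other had every correlation of same-numbered libraries above 0.1 (16 of 24 over all pairs of groups, -0.276 to 0.676). WT control and slincRosu3 TCDD, which meet only in the difference and the average of effects, did (4 of 4, 0.125 to 0.421). The highest, 0.676, joined WT control 4 and slincRosu3 control 4, which both stand apart on the first component, as does WT TCDD 4. As a hint from the data, not the design, in 13 of 24 same-numbered pairs the library with the same number was the best correlated of the 4 in the other group. Pairing is therefore not excluded. With the block, adjusted p of prl (0.0641) and cxcl12b (0.0585) for TCDD in WT, cfd (0.0589) for TCDD in slincRosu3, hsd3b2 (0.0561) without TCDD, hsp70.3 (0.0519) and cyp1c1 (0.058) with TCDD, and the bone (0.0867) and Nrf2 (0.0533) lists for the difference of effects were above 0.05, and no other named call was lost. A fit of only the groups compared gave 26 (26 higher, 0 lower) for TCDD in WT and 149 (62 higher) for the lines without TCDD, and moved the share higher with TCDD from 47.6% to 57.6%. The DESeq2 Wald test gave 147 (119 higher, 81% against 91.2%), 157 (138 higher), 499 (215 higher) and 674 (335 higher) genes for TCDD in WT, in slincRosu3 and the lines without and with TCDD. Without the 4 libraries the counts were 327 (237 higher, 72.5%), 170 (152 higher), 604 (301 higher), 697 (330 higher) and, for the difference of effects, 20. Without WT control 1 and 2 together they were 27 for TCDD in WT, 109 (32.1% higher against 42.4%) for the lines without TCDD and 0 for the difference. The WT libraries alone, on the table before the authors' filter and with no filter on low counts, gave 30 genes for TCDD in WT, close to the 26 of the fit of the WT groups, and these 3 choices changed together. Leaving out 1 library gave 46 to 76 genes for TCDD in WT, 46 to 82 in slincRosu3 (46, 53 and 51 without control 1, control 2 and TCDD 1), 176 to 328 without TCDD (176, 198 and 187 without slincRosu3 control 1, 2 and 3), 175 to 315 with TCDD (243 without WT TCDD 1; 175, 194 and 180 without slincRosu3 TCDD 1, 2 and 4) and 0 to 0 for the difference. With an estimated correlation the lists past the threshold fell from 12 to 2, 10 to 2, 5 to 0, 3 to 0 and 16 to 0; with fry they numbered 3, 5, 1, 1 and 0, and with its groups in reverse order 3, 4, 1, 1 and 0. Fewer libraries lower the counts by construction in part; otherwise the cause was not tested. The averaged TCDD effect gave 168 genes, 266 by DESeq2 and 486 without the 4 libraries. Of 135 named gene results 51 lost a call under some alternative and 0 reversed. The table used already is the authors' filtered one, so that alternative gives no separate value, and no alternative on BigD was run. Depth limits genes of few counts such as mhc1uma and mhc1ula.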

Other observations

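The TCDD effect averaged over both lines was added after the data were seen, and the genes named here were chosen after their values were seen.

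Averaged over WT and slincRosu3, 168 genes changed with TCDD by edgeR's quasi-likelihood test, 151 higher and 17 lower, and 77 of them were called in neither line alone (67 higher, 10 lower). Among these 77, log2 changes were 1.23 for the cell adhesion gene ncam3, 0.73 for the adrenomedullin gene admb, 1.18 for the endothelial gene plvapa, 0.47 for nfe2l2a, which encodes the Nrf2 transcription factor, 0.48 for the matrix gene thbs1b and 0.4 for acvrl1, a receptor gene of blood vessels. Of the 26 lists, 4 hold with an estimated correlation: AHR target genes (14 of 18 higher; adjusted p = 1.07e-05), Nrf2 (3 of 22 higher; 0.0256), Wnt signalling (3 higher and 1 lower of 26; 0.0196) and matrix remodelling (4 of 24 higher; 0.0196). The count was 486 without the 4 libraries high on the first component and 266 by DESeq2. The average of sox9b was -0.55 and did not pass (adjusted p = 0.153).

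In the authors' deposited DESeq2 results, 143 genes had an adjusted p under 0.05 for TCDD in WT, 499 for slincRosu3 against WT without TCDD and 671 with TCDD, and 68, 317 and 384 of these were among those called here by edgeR. The authors also compared slincRosu3 with TCDD against WT control, a contrast of line and treatment together, with 908 genes, 532 higher and 376 lower. There sox9b had a log2 change of -0.82 (adjusted p = 0.00958 by the authors' DESeq2), although neither line nor treatment alone passed for it here.

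In the first sheet of raw counts, 12 of the 12 WT columns checked held values that the second sheet and the main table give to another WT library.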
